A study of Homo sapiens with 6 samples.

How the data were processed

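Gene expression was measured in 6 cultures of MDA-MB-231, an established human line of triple-negative breast cancer. The cells carried a control short hairpin RNA (shRNA) or 1 of 2 shRNAs, 162 and 159, against TIP-1, the protein encoded by TAX1BP3. Each of the 3 groups held 2 independent clones, each measured on a single array with no technical replicates, so clones are the replicates (n = 2 per group). Per the labels, the cells were grown in RPMI medium with fetal bovine serum, trypsinised, reseeded and kept in culture overnight before total RNA was taken. Labelled target was hybridised to Affymetrix Human Gene 1.0 ST arrays.

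The deposited values are log2 signals per probe set, normalized by the authors with the Affymetrix Exon Array Computational Tool. Their settings for background correction, normalization and summarization are not given in the sources used here. The log2 base was inferred from the range of the values, 2.29 to 14.65. The value table had 33297 rows on 6 arrays. Of these, 19461 carried 1 gene symbol, 1753 carried several and 12083 carried none. The 21214 rows with at least 1 symbol were tested. Symbols came from the platform's probe table, with 1 symbol updated through its Entrez ID. Of the tested rows, 403 repeated the values of an earlier row on every array. Arrays give no count depth, and the number of arrays limits the precision. Probe-level data and detection calls were not used here.

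The values were used without further scaling. One linear model with 3 groups was fitted per row with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 3 residual degrees of freedom, 5.31 prior degrees of freedom). The comparisons were TIP-1 shRNA (the mean of both hairpin groups) minus control, each hairpin minus control, and shRNA 159 minus shRNA 162. Tests were two-sided. A row passed at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p values below come from limma unless another test is named. This model takes its error from the spread between clones of the same hairpin, not from the spread between hairpins, which is why fits that use the latter are given beside the main count.

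The overlap of the hairpins was set beside independent lists and 100 simulations of unchanged groups that share their controls. TAX1BP3 was also tested with an exact permutation test of the 4 shRNA clones against the control clones. In all, 34 gene lists (1095 genes, 1003 measured, at least 5 measured per list) covered TIP-1 partners, signalling, adhesion, matrix, metastasis, stress, metabolism and markers of other cells. They were tested with limma's camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists of each comparison, and again with an estimated correlation and with fry. The result of 1 list is not reported here, though it counts among the lists tested and passed. A gene with several rows entered by its row with the highest mean. Genes were ordered along the chromosomes with the RefSeq annotation of assembly GRCh38.p14, which placed 18369 of 18418 genes with a row of their own. Means over windows of 15 consecutive genes were compared with 1000 random gene orders, and windows beyond the limits of their highest and lowest windows at a two-sided level of 0.05 were joined into runs. The same scan was made of the differences between clones of the same group. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

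The groups, the tests, the gene lists, most alternatives and the rule for named genes were chosen before the data were examined. The rule named TAX1BP3 and, among rows with 1 symbol that passed and whose clones of the compared groups did not overlap, the 12 largest increases and 12 largest decreases for TIP-1 shRNA minus control, the 4 largest each way per hairpin and the 6 largest each way between hairpins. It also named up to 4 members of each described list with the smallest p. The rule excluded loci that do not encode a protein. This exclusion was first left out by mistake and applied after the values were seen, when LCP1 replaced the long non-coding RNA UCA1 (log2 change -1.64) among the decreases with shRNA 159. Other genes were named after their values were seen, and the text says so.

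The alternatives were the brighter rows only, all rows, quantile normalization, a variance trend, a replicate block, leaving out each array, only the 4 arrays compared, the 4 shRNA clones as 1 group, and the hairpin as a random block. Leaving out the chromosome 7 run, leaving out the genes of any run from the lists, counting identical rows once and requiring a 2-fold change were added after seeing the data. The scan along the chromosomes was also added then. The fit was tested on simulated independent rows with the spread between clones of the same group. Changes were planted in both hairpins or in shRNA 159 alone. The latter counted as true changes of TIP-1 shRNA minus control, at 0.5 times their size. For that comparison the fit recovered 5% of changes of 0.25 on the log2 scale, 79.0% of changes of 0.5 and 99.3% of changes of 1, with 5.39% false calls. Changes of 0.5 were recovered at 56.4% for shRNA 162, 68.7% for shRNA 159 and 58.3% for the difference between them. Small changes can thus be missed, and a low count of passing genes does not show that a list was unchanged. For shRNA 162, shRNA 159 and the difference between them, false calls made up 5.95%, 6.44% and 6.49%. No spread between hairpins or clone origins was simulated, so these rates do not cover calls that come from it.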

Results

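Transcript levels were measured on 6 arrays from MDA-MB-231 cells, 2 independent clones each with control shRNA, TIP-1 shRNA 162 and TIP-1 shRNA 159. TIP-1 (gene TAX1BP3) is a small protein made mostly of a PDZ domain, which binds the carboxyl ends of partners such as beta-catenin. The array medians lay between 7.37 and 7.44 on the log2 scale. Clones of the same group correlated at 0.997 (control), 0.997 (shRNA 162) and 0.996 (shRNA 159) across the tested rows, which are not independent replicates. At most 6 rows differed by 2-fold or more between clones of the same group, against 51 to 107 between clones of different groups. The first principal component held 46.2% of the variance and set the shRNA 162 clones apart from the other 4 arrays. The second, with 27.8%, set the control clones apart from the shRNA 159 clones.

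The targeted gene was lower with both hairpins. The TAX1BP3 row stood at 11.61 ± 0.07 in the control clones, 9.93 ± 0.11 with shRNA 162 and 10.40 ± 0.001 with shRNA 159 (log2, mean ± SD, n = 2 each). TAX1BP3 fell by 1.67 on the log2 scale with shRNA 162 (SE 0.08, limma adjusted p = 4.4e-05), which left 31.3% of the control level. With shRNA 159 it fell by 1.20 (SE 0.08, limma adjusted p = 0.00034), which left 43.4%. The hairpins differed by 0.47 (limma adjusted p = 0.013). All 4 shRNA clones lay below both control clones, and the exact two-sided permutation test gave p = 0.0667, the smallest that 15 splits allow. The row is also annotated to the readthrough transcript P2RX5-TAX1BP3, so the signals of both cannot be separated. The neighbouring P2RX5 row changed by 0.24 (SE 0.07, limma adjusted p = 0.098) for TIP-1 shRNA minus control and did not pass.

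**Figure D1:**
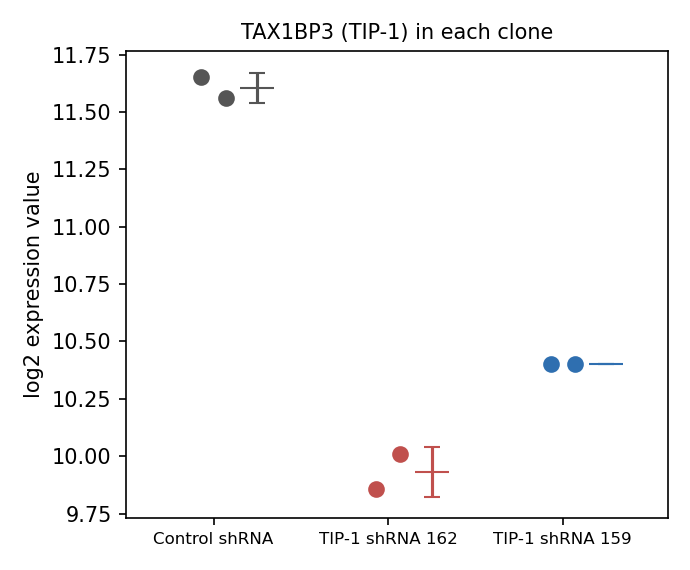
Expression of the TAX1BP3 row on the log2 scale in each of the 6 clones (points), with the mean and SD of each group (bars, n = 2). The shRNA 162 clones (9.93 on average) and the shRNA 159 clones (10.40) lie below the control clones (11.61); the axis does not start at 0.

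TIP-1 shRNA minus control asks which transcripts differed from control when both hairpins are weighted equally. TULP3, a protein of ciliary trafficking, rose by 1.83 on the log2 scale (SE 0.11, 3.54-fold) and CDK6, a kinase of the G1 phase, by 1.26 (SE 0.09, 2.39-fold). BCHE (butyrylcholinesterase), a dim row in the control clones, rose in signal by 1.90 (SE 0.13). LCP1, the actin-bundling protein L-plastin, fell by 1.83 (SE 0.07), F2RL2, a protease-activated receptor, fell by 1.75 (SE 0.10), and HAS2, a hyaluronan synthase, was 2.82-fold lower. The cytidine deaminase CDA fell by 1.49, the G protein regulator RGS4 fell by 1.42, the granzyme B inhibitor SERPINB9 fell by 1.38 and the receptor CD96 fell by 1.28. Each of these genes passed with either hairpin alone, in the same direction in 4 of 4 shRNA clones.

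Of the 24 named genes, 17 differed between the hairpins, LCP1, CDA, RGS4 and SERPINB9 among them. PHGDH, the first enzyme of serine synthesis, had a mean change of -1.96, made of -3.58 with shRNA 162 and -0.35 with shRNA 159. CYP24A1, the enzyme that inactivates vitamin D, changed by -2.16 with shRNA 162 and -0.23 with shRNA 159. The GABA receptor subunit GABRA3 changed by 0.13 with shRNA 162 and by 2.69 with shRNA 159. GRPR, the receptor of gastrin-releasing peptide, rose by 2.15 and 0.77. The chromatin remodeller SMARCA1 fell by 2.05 and 0.95, and CPED1 fell by 1.64 and 0.65. SPANXB1 fell by 1.69 and 1.25, but it belongs to a family of nearly identical copies and is read by a pair of identical rows, so its identity is uncertain. Of the 12 named increases, 8 lie in one run of neighbouring genes on chromosome 7: ELAPOR2 (0.47 with shRNA 162, 3.29 with shRNA 159), TMEM243 (0.88, 2.39), SLC25A40 (0.66, 2.37), DBF4 (0.64, 2.37), SEMA3A (1.32, 1.60), DMTF1 (0.75, 1.91), CROT (0.38, 2.22) and CDK6 (1.22, 1.30). BCHE (3.76 ± 0.12, n = 2), DBF4 (5.79 ± 0.01) and GABRA3 (5.98 ± 0.01) were dim in the control clones, below the lower quartile of every array; changes against rows this dim, which were not shown to be above background, are differences in array signal and not exact changes in transcript level.

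In this comparison 980 of 21214 rows passed, 639 higher and 341 lower (4192 rows at an unadjusted p under 0.05). Of these, 21 rose and 18 fell by 2-fold or more. After quantile normalization the direction was more balanced, with 549 higher and 465 lower. The count rests on the spread between clones of the same hairpin. With the 4 shRNA clones as 1 group 71 rows passed. With the hairpin as a random block 27 passed, 6 of them in the chromosome 7 run. Neither fit takes the hairpins as the replicates. Among the 27 were 10 of the 24 named genes (BCHE, TULP3, SEMA3A, CDK6, F2RL2, HAS2, SPANXB1, RGS4, SERPINB9 and CD96). Without control clone 1 or 2 the count was 187 or 197, and without shRNA 162 clone 1 or 2 it was 551 or 456.

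**Figure D2:**
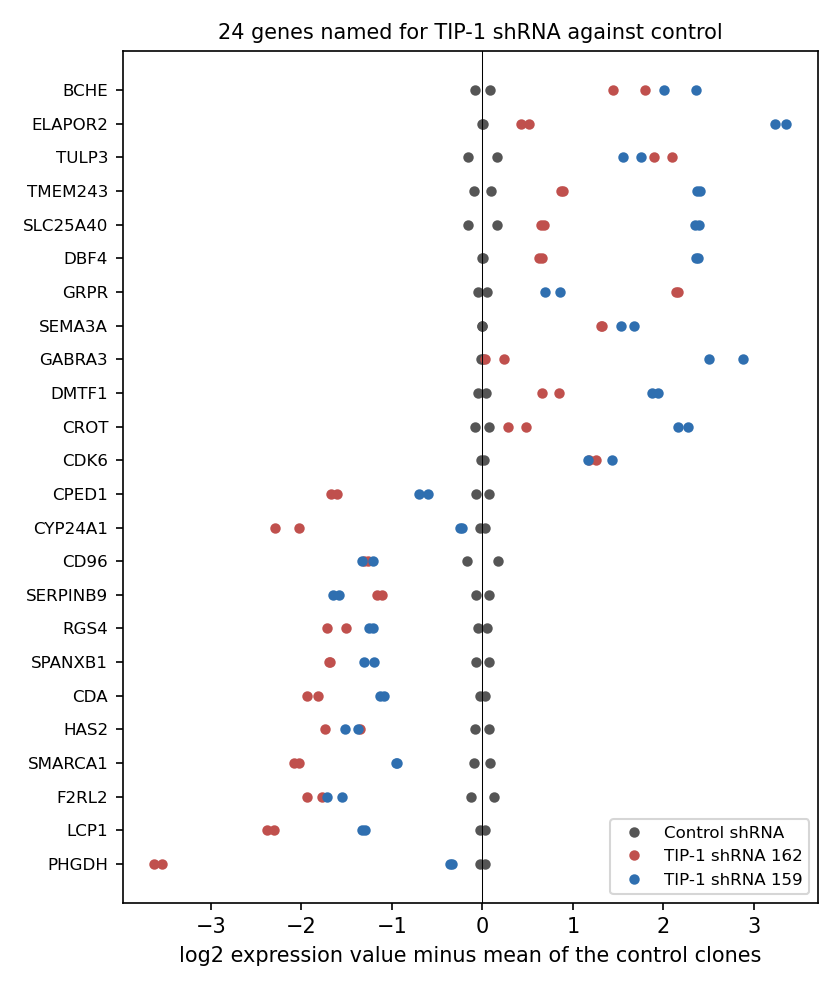
Change of the 24 named genes in each clone, as the log2 value minus the mean of the control clones (grey, control; red, shRNA 162; blue, shRNA 159). BCHE, TULP3, SEMA3A and CDK6 lie above 1 and LCP1, F2RL2, HAS2, CD96, RGS4 and SERPINB9 below -1 with both hairpins, whereas PHGDH moved mostly with shRNA 162 (-3.58) and ELAPOR2 mostly with shRNA 159 (3.29).

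Among the 34 lists, 8 passed camera for TIP-1 shRNA minus control, 7 lower and 1 higher. In the matrix protease list, 4 of 47 genes fell and 3 rose (5 and 3 adjusted over the list alone), with ADAMTS1 at -0.97, TIMP3, an inhibitor, at -0.75, SERPINE2 at -0.42 and ADAMTS6 at 0.49 (camera adjusted p = 0.00081; adjusted p = 0.607 with an estimated correlation). Of 12 genes linked to bone metastasis of this line, 3 fell, FGF5 (-0.42) and CCN2 (-0.31) among them, and FST rose by 0.32 (6 and 1 adjusted over the list alone; camera adjusted p = 0.0041; adjusted p = 0.607 with an estimated correlation). In the type I interferon list, 8 of 46 rose and 0 fell (13 and 0 adjusted over the list alone), with IFI44 at 1.05, SAMD9 at 0.96, IFIT2 at 0.83 and IFIT1 at 0.77 (camera adjusted p = 0.0079; adjusted p = 0.607 with an estimated correlation). SAMD9 lies in the chromosome 7 run. Antigen presentation was lower, with HLA-DMA at -0.57 as the 1 of 15 genes that fell (2 adjusted over the list alone; camera adjusted p = 0.014; adjusted p = 0.607 with an estimated correlation).

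In the hypoxia and glycolysis list, 5 of 40 fell (6 adjusted over the list alone), with the collagen-modifying PLOD2 at -0.67, the aldolase ALDOC at -0.54, HIF1A at -0.54 and BNIP3 at -0.33 (camera adjusted p = 0.017; adjusted p = 0.742 with an estimated correlation). In the actin cytoskeleton list, 2 of 46 fell, PFN2 at -0.32 and CFL2 at -0.33, and SVIL rose by 0.35 (7 and 3 adjusted over the list alone; camera adjusted p = 0.024; adjusted p = 0.607 with an estimated correlation). In the extracellular matrix list, 6 of 53 fell and 1 rose (8 and 1 adjusted over the list alone), with COL12A1 at -0.56, FBN1 at -0.50, SRGN at -0.34 and the crosslinking enzyme LOXL2 at 0.41 (camera adjusted p = 0.036; adjusted p = 0.742 with an estimated correlation). LOXL2 lies in a run of neighbouring genes on chromosome 8. With an estimated correlation 0 of 34 lists passed, fry called 2 (interferon and ribosomal proteins, both higher), and without shRNA 159 clone 2 camera called 4. Among the brighter rows alone 6 lists passed, 0 of them higher, and the interferon, extracellular matrix and antigen presentation lists lost the call. With shRNA 159 minus control, 0 of 46 actin genes passed, and neither the actin list (camera adjusted p = 0.974) nor the extracellular matrix list (0.915) did. The matrix protease (0.051), bone metastasis (0.098) and antigen presentation (0.099) lists did not pass there either. The hypoxia and glycolysis list did not pass with shRNA 162 minus control (camera adjusted p = 0.473).

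The other 26 lists did not pass for TIP-1 shRNA minus control. Members that rose and fell numbered 1 and 1 of 21 Wnt/beta-catenin targets (MYC 0.43, WNT5A -0.52), 1 and 2 of 39 integrin and focal adhesion genes, 2 and 3 of 48 cadherins and adhesion molecules, 1 and 0 of 27 epithelial genes (EPCAM 0.55) and 2 and 2 of 36 mesenchymal genes (SNAI1 0.60, SNAI2 -0.45). They numbered 0 and 1 of 19 lung metastasis genes, 2 and 1 of 42 NF-kB genes and cytokines (IL1A 0.84, IL6 0.56, IL1B -0.59), 2 and 2 of 25 TGF-beta targets, 2 and 3 of 26 YAP/TAZ targets (NUAK2 0.59, IGFBP3 -0.65, F3 -0.52) and 3 and 3 of 28 ERK response genes (ETV5 -0.58). Of 47 EGFR ligands and receptor kinases 0 rose and 3 fell (EPHA4 -0.61, EFNB2 -0.57, TGFA -0.43), and of 46 axon guidance genes 4 rose and 1 fell (SEMA3A, SEMA3E 0.43, PLXNA1 0.44, SLIT2 -0.59). For S phase and mitosis the counts were 1 and 0 of 57, for p53 targets 1 and 0 of 27, for apoptosis regulators 3 and 0 of 35, for the unfolded protein and amino acid response 1 and 2 of 40, for cholesterol synthesis 2 and 0 of 21, for oxidative stress 1 and 0 of 33 and for small RNA machinery 1 and 0 of 17. No member passed among 10 TIP-1 partners, 39 ribosomal proteins, 40 histones, 19 luminal, 18 fibroblast and endothelial, and 16 melanocyte and neural markers. Of 19 leukocyte markers, LCP1 and LAPTM5 fell and 0 rose. In runs of neighbouring genes lie MYC on chromosome 8, EPCAM on 2, SEMA3A and SEMA3E on 7 and ETV5 on 3. So do the 3 apoptosis regulators, 2 cholesterol genes, 1 p53 target and 1 oxidative stress gene that rose, and 1 of the TGF-beta and 1 of the YAP/TAZ targets that passed. For 10 of these 26 lists the median and the mean change differed in sign.

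With shRNA 162 the largest change was in MAGEB2, a cancer/testis antigen, which rose from 5.37 ± 0.04 to 10.60 ± 0.05 (log2, mean ± SD, n = 2 each; limma adjusted p = 2.3e-07). Its levels in the control and shRNA 159 clones (5.55 ± 0.24) lie below the lower quartile of every array, so its changes are differences in array signal alone. The mesenchymal cadherin CDH11 rose by 1.91 (SE 0.10), beside GRPR and TULP3 at 2.15 and 2.00. PHGDH fell from 10.22 ± 0.04 to 6.64 ± 0.06, a change of -3.58 (SE 0.08, limma adjusted p = 2.3e-07). The smooth muscle actin ACTG2 fell by 2.93 (SE 0.09), LCP1 fell by 2.34 (SE 0.08) and SERINC2 fell by 2.21 (SE 0.09). A dimmer SERINC2 row changed by -0.37 and did not pass (limma adjusted p = 0.118).

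With shRNA 162 the actin, extracellular matrix, matrix protease, bone metastasis and antigen presentation lists were lower. Of 46 actin cytoskeleton genes 8 fell and 1 rose (13 and 4 adjusted over the list alone), with CALD1 at -0.73, CFL2 at -0.56, MYL9 at -0.52 and ACTN1 at -0.48 (camera adjusted p = 0.00065; adjusted p = 0.525 with an estimated correlation). Of 53 extracellular matrix genes 12 fell, FBLN1 (-0.78), FN1 (-0.71) and SRGN (-0.53) among them, and LOXL2 rose by 0.75 (13 and 1 adjusted over the list alone; camera adjusted p = 0.00065; adjusted p = 0.594 with an estimated correlation). Of 47 matrix protease genes 10 fell and 2 rose (12 and 2 adjusted over the list alone), with CTSZ at -0.58 (camera adjusted p = 0.00065; adjusted p = 0.525 with an estimated correlation). Of 12 bone metastasis genes 4 fell and 0 rose (4 and 0 adjusted over the list alone; camera adjusted p = 0.00065; adjusted p = 0.594 with an estimated correlation). Of 15 antigen presentation genes 2 fell (5 adjusted over the list alone; camera adjusted p = 0.012; adjusted p = 0.525 with an estimated correlation).

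Higher with shRNA 162 were cholesterol synthesis and the interferon list. Of 21 cholesterol genes 3 rose, SQLE by 0.98, CYP51A1 by 0.59 and HMGCS1 by 0.45 (6 adjusted over the list alone; camera adjusted p = 0.0065; adjusted p = 0.525 with an estimated correlation). SQLE and CYP51A1 lie in runs on chromosomes 8 and 7, and without the genes of runs the cholesterol list had a camera adjusted p = 0.064. Of 46 interferon genes 9 rose and 2 fell (11 and 4 adjusted over the list alone), with IFIT1 at 1.46, IFIT2 at 1.46, SAMD9 at 1.24 and SAMD9L at 1.02 (camera adjusted p = 0.043; adjusted p = 0.525 with an estimated correlation). SAMD9 and SAMD9L lie in the chromosome 7 run, and without the genes of runs the interferon list had a camera adjusted p = 0.168. With shRNA 162, 2019 rows passed, 1247 higher and 772 lower (1081 and 1065 after quantile normalization), and 48 rose and 42 fell by 2-fold or more. Without control clone 1 or 2 the count was 526 or 636, and without shRNA 162 clone 1 or 2 it was 697 or 570.

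With shRNA 159 the largest increases were ELAPOR2 at 3.29 (SE 0.08, 9.80-fold), GABRA3 at 2.69 (SE 0.13), TMEM243 at 2.39 (SE 0.09) and DBF4, the activating subunit of a replication kinase, at 2.37 (SE 0.07). ELAPOR2, TMEM243 and DBF4 lie in the chromosome 7 run. F2RL2 fell by 1.64 (SE 0.11), SERPINB9 fell by 1.62 (SE 0.08), HAS2 fell by 1.44 (SE 0.13) and LCP1 fell by 1.31 (SE 0.08). Of 40 hypoxia and glycolysis genes 3 fell, PLOD2 at -0.70, ALDOC at -0.64 and the hexokinase HK2 at -0.48, while EPAS1 rose by 0.93 and lies in a run on chromosome 2 (9 fell and 1 rose adjusted over the list alone; camera adjusted p = 9.3e-06; adjusted p = 0.822 with an estimated correlation). Of 48 cadherins and adhesion molecules PCDH20 fell by 0.59 and ICAM1 rose by 0.45, in a list that was lower (4 and 1 adjusted over the list alone; camera adjusted p = 0.0091; adjusted p = 0.822 with an estimated correlation). Of 46 interferon genes 3 rose, IFI44 by 0.97, SAMD9 by 0.69 and SAMD9L by 0.52 (6 adjusted over the list alone; camera adjusted p = 0.0091; adjusted p = 0.822 with an estimated correlation). Without the genes of runs the interferon list had a camera adjusted p = 0.053. In all 537 rows passed with shRNA 159, 359 higher and 178 lower (307 higher without the chromosome 7 run), and 31 rose and 13 fell by 2-fold or more. Without control clone 1 or 2 the count was 182 or 142, and without shRNA 159 clone 1 it was 247.

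The overlap asks which changes both hairpins shared. BCHE, TULP3, SEMA3A and CDK6 rose, and LCP1, F2RL2, HAS2, CDA, RGS4, SERPINB9, CD96, SPANXB1 and TAX1BP3 fell, by 2-fold or more with each hairpin. In all, 231 rows passed with both hairpins in the same direction, 159 higher and 72 lower, against 21.1 and 6.48 expected of independent lists. Without the chromosome 7 run 122 were higher and 72 lower. Independent lists leave out the shared controls, so part of the excess can come from these. In simulated groups without any change 0.01 rows passed with both. Almost no row can pass in such groups, so this value does not measure what the shared controls add. Of the 231, 172 did not pass for the difference between the hairpins and 59 did. Another 16 rows passed in opposite directions. Across rows the changes correlated at 0.415 (Spearman 0.428), below the 0.479 to 0.532 that shared controls alone gave in simulations, but their covariance was 0.0175 against 0.00628 simulated. With a different control clone for each hairpin the correlation was 0.216 or 0.320. The overlap was 60 or 62 rows without control clone 1 or 2, 108 or 92 without shRNA 162 clone 1 or 2, and 144 without shRNA 159 clone 1.

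**Figure D3:**
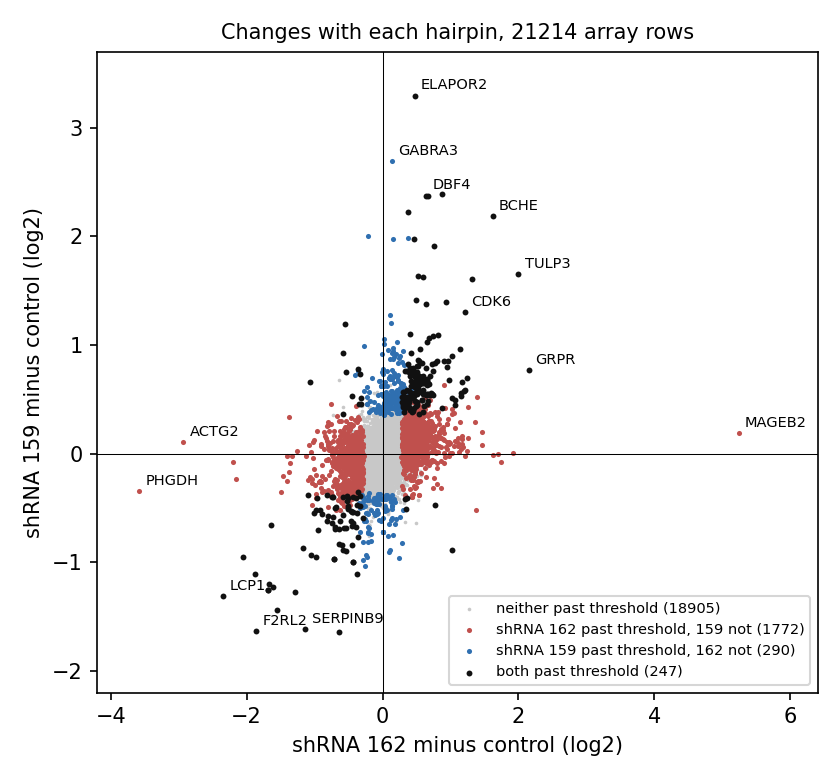
Log2 change with shRNA 162 (x axis) against that with shRNA 159 (y axis) for 21214 array rows, coloured by which hairpin passed. In black are the 247 rows that passed with both; 1772 passed with shRNA 162 alone (red; MAGEB2, dim in the control clones, at a signal difference of 5.24) and 290 with shRNA 159 alone (blue, GABRA3 at 2.69).

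The direct comparison of the hairpins asks which transcripts differed between clones that share the target. Higher with shRNA 159 were PHGDH by 3.23 (SE 0.08, 9.41-fold), ACTG2 by 3.04 (SE 0.09), ELAPOR2 by 2.82, GABRA3 by 2.56, SERINC2 by 2.13 and CYP24A1 by 1.92. Lower with shRNA 159 were CDH11 at -1.91, the kinase CDK15 at -1.91, the epidermal protein FLG at -1.89 and the nucleosome-binding protein HMGN5 at -1.64. MAGEB2 and LRRN1 were also lower, with signal differences of -5.05 and -1.81 against rows that were dim with shRNA 159 (5.55 and 4.68). In actin cytoskeleton 6 of 46 genes were higher with shRNA 159 and 0 lower (7 and 1 adjusted over the list alone; camera adjusted p = 0.00075; adjusted p = 0.746 with an estimated correlation). In extracellular matrix 13 of 53 were higher and 3 lower (16 and 4 adjusted over the list alone; camera adjusted p = 0.0032; adjusted p = 0.746 with an estimated correlation). In cholesterol synthesis 5 of 21 were lower and 0 higher (9 and 0 adjusted over the list alone; camera adjusted p = 0.0023; adjusted p = 0.746 with an estimated correlation). In hypoxia and glycolysis 9 of 40 were lower and 3 higher (12 and 3 adjusted over the list alone; camera adjusted p = 0.016; adjusted p = 0.746 with an estimated correlation). In all 1836 rows passed, 852 higher and 984 lower with shRNA 159 (1039 and 898 after quantile normalization). The count was 597 or 651 without shRNA 162 clone 1 or 2 and 1204 without shRNA 159 clone 2.

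Changed genes lay side by side along several chromosomes. Of 459 genes that passed with shRNA 159, 123 (26.8%) lay in runs, which held 1.36% of the ordered genes. The shares were 6.76% against 1.17% with shRNA 162 and 10.2% against 1.61% between the hairpins. The runs were found from these same changes. From BUD23 to CASD1 on chromosome 7, 95 neighbouring genes had a median change of 0.54 with shRNA 159, and 52 of them passed. In the same run 41 genes passed as higher with shRNA 162, for which 21 genes from CFAP69 to GNGT1 formed a run of their own (median 0.46, 13 passed). The medians of the run were 0.52 and 0.51 in the shRNA 159 clones and 0.27 and 0.32 in the shRNA 162 clones, each minus the control mean. With shRNA 159 a run of 46 genes on chromosome 9 (VLDLR-AS1 to BNC2, median 0.33) and 4 runs on chromosome 2 were higher, and 33 genes on chromosome 17 (SNORD4B to CRLF3, median -0.25) were lower. With shRNA 162, 38 genes from CLU to TPT1P8 on chromosome 8 were higher (median 0.64), as were 24 from PDLIM2 to GNRH1 and 22 from ANXA13 to GSDMC. On chromosome 3, 40 genes from CLDN11 to KLHL6 (median -0.48), 40 from EIF2B5 to RTP1 and 29 from LINC00885 to ANKRD18DP were lower. Between clones of the same group the scan also found 11 runs, with medians from -0.27 to 0.21, among them 38 genes from ATP13A1 to ZNF254 on chromosome 19 (0.21 between the control clones, 0.19 between the shRNA 159 clones), and the median of the chromosome 17 run lies within that range. A window mean as high as the highest on chromosome 7, 1.67, came up in none of 1000 random gene orders, and the largest window mean between clones of the same group was 0.267 in size.

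**Figure D4:**
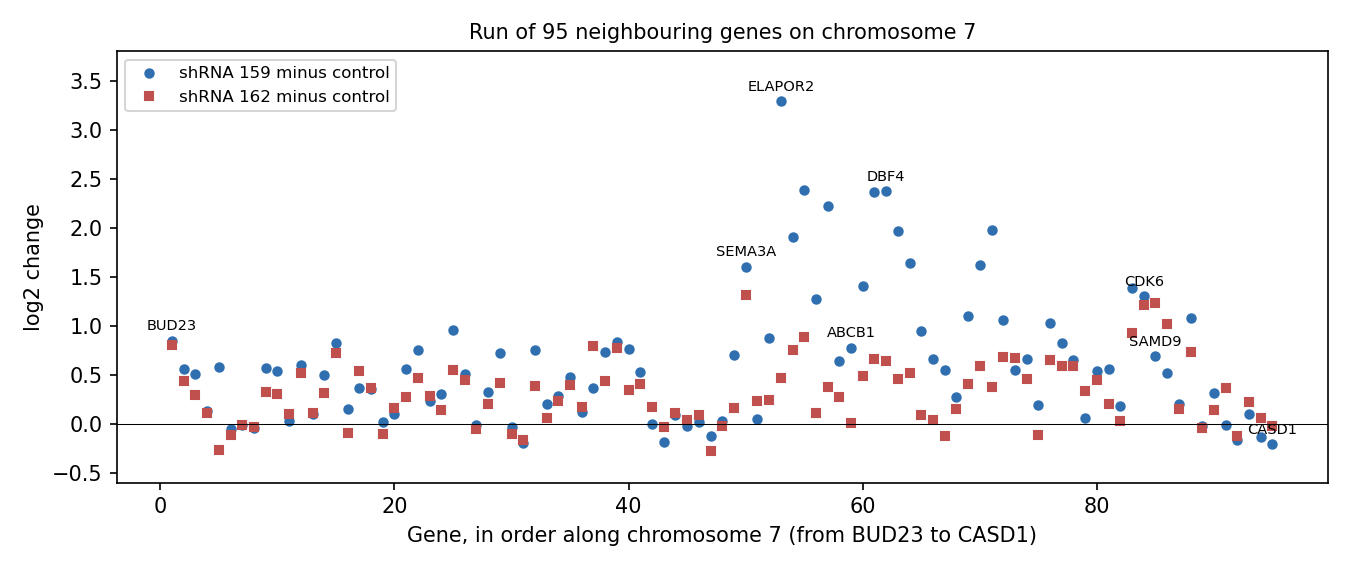
Log2 change of 95 neighbouring genes on chromosome 7, in their order from BUD23 to CASD1, with shRNA 159 (blue) and shRNA 162 (red), each minus control. The medians over the run were 0.54 with shRNA 159, where ELAPOR2 reached 3.29, and lower with shRNA 162 (clones 0.27 and 0.32).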

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

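The tests of random gene orders, of target depletion for all 3 patterns, of a single clone for the interferon genes, of pairs of clones against the other 4 arrays and of lists without the genes of runs were chosen after the results were seen.

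The hairpins share a target, yet 1836 rows differed between them (shRNA 159 minus shRNA 162, tested in the limma fit). Depth of depletion differed too, with TAX1BP3 0.47 higher with shRNA 159, but 259 rows moved further from control with shRNA 159, which depletes less (past the threshold against control and between the hairpins in the same direction, with the larger change in size; 172 of them outside runs), against 119 false calls that the threshold allows, and this argues against unequal depletion as the whole cause, if effects grow with depletion. Level-dependent normalization is argued against as well, since 90.7% of the 1836 rows stayed called after quantile normalization. Of the 15 ways to pair the arrays into 3 groups, 1 gave as many rows on the F test (real 2315, highest other 361), which is too few ways for a share under 0.05; setting the shRNA 162 clones against the other 4 arrays called 1319 rows, against 102 for the shRNA 159 clones, 71 for the control clones and 0 for each pair of clones from different groups, which points to a structure in which the shRNA 162 clones stand apart. Effects of a hairpin beyond TIP-1 and differences between the cells from which the clones were drawn may each contribute, and neither was tested, because each hairpin has its own clones.

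The chromosome 7 run was higher in both shRNA 159 clones (medians 0.52 and 0.51) and, by less, in both shRNA 162 clones (0.27 and 0.32). With shRNA 162, 21 genes from CFAP69 to GNGT1 formed a run. The difference was uneven: 41 genes from PHTF2 to GATAD1 formed a run between the hairpins (median 0.37, 22 passed). Of the named genes, ELAPOR2 differed by 2.82, CROT by 1.84, DBF4 by 1.73, SLC25A40 by 1.71, TMEM243 by 1.51 and DMTF1 by 1.15. SEMA3A and CDK6 did not pass for the difference (limma adjusted p = 0.060 and 0.661). GSAP, SAMD9 and SAMD9L were lower with shRNA 159 (-0.43, -0.55 and -0.51). Random placement is argued against, as none of 1000 random gene orders gave a window as high as the real 1.67. Windows between the control clones and between the shRNA 159 clones passed this test too (largest 0.267 in size), so only the size sets the run apart. Level-dependent normalization is also argued against, as 475 genes of matched level had a median change of 0.00109 (-0.0114 to 0.0133). These matched genes were drawn from outside every run. The run's own median, 0.535, comes from genes selected as high with shRNA 159, so the contrast in size is partly built in. Depletion of TIP-1 alone is argued against as the whole cause, if effects grow with depletion, because in a scan of the difference itself the highest window, 1.29, lay on chromosome 7 and was higher with shRNA 159 (limit of random orders 0.412), although the target fell further with shRNA 162. A candidate explanation is a gain of copies of the region, in the shRNA 159 clones or in both hairpins' clones, and it stays open. Of 55 brighter genes, 70.9% changed by over 0.5 on the log2 scale with shRNA 159 (57.1 to 82.4%). This lies between the bounds of 75% and 50% set before the share was computed. The share cannot decide, because the same shRNA 159 values placed these genes in the run. The interval also treats neighbouring genes as independent. Every change from control is set against the same control clones. For the rise that both hairpins share, a difference in the control clones therefore cannot be told apart from one in the hairpins' clones. The difference between the hairpins, with its highest window of 1.29, uses no control clone and cannot come from one. DNA was not analysed here, and a gain in several clones may have come from a shared origin, which was not tested.

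Of 46 interferon genes 9 rose and 2 fell with shRNA 162. Members chosen by their rise in a single clone of it changed in the other clone too. The median ratio was at least 0.843 in each of the 4 ways of choosing clone and control (intervals from 0.531 up). This argues against a single clone carrying the change. The intervals treat the 8 or 7 members chosen as independent, and each clone was measured on 1 array. Of the 46 genes, 10 passed for the difference between the hairpins, in either direction. Of the 9 that rose with shRNA 162, 7 passed as lower with shRNA 159 than with shRNA 162, which choosing them for that rise favours. Whether depletion of TIP-1 alone may account for the rise stays open. Over the 9 members the median ratio of the changes, 159 to 162, was 0.221. Its interval of 0.0802 to 0.559 spans the bound of 0.359 (0.5 times the target's own ratio). Choosing members for their rise with shRNA 162 also lowers this ratio. An earlier form of this test used all 46 genes and favoured a shared effect, with medians of 0.0978 with shRNA 162 and 0.0682 with shRNA 159 and a camera adjusted p = 0.763 for the difference; it was replaced after that was seen, because most of the list did not change. The list lost its call with shRNA 162 without the genes of runs (camera adjusted p = 0.168). A response to the hairpin itself was not tested.

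Further differences between the hairpins, each shRNA 159 minus shRNA 162 and past the threshold in the limma fit, were 3.23 for PHGDH, 3.04 for ACTG2, 2.56 for GABRA3, 2.13 for SERINC2, 1.92 for CYP24A1, 1.10 for SMARCA1, 1.03 for LCP1, 0.99 for CPED1, 0.77 for CDA, 0.44 for SPANXB1 and 0.38 for RGS4. Lower with shRNA 159 were CDH11 (-1.91), CDK15 (-1.91), FLG (-1.89), HMGN5 (-1.64), GRPR (-1.38) and SERPINB9 (-0.48). MAGEB2 and LRRN1 were lower by signal differences of -5.05 and -1.81, against rows that were dim with shRNA 159 and not shown to be above background. Opposite calls with the hairpins were found in 16 rows. Gene lists that differed had median differences of 0.070 for extracellular matrix, 0.052 for actin cytoskeleton, -0.134 for hypoxia and glycolysis and -0.214 for cholesterol synthesis, and all lost the call with an estimated correlation (adjusted p = 0.746 each).

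Among the 12083 rows without a gene symbol, which the comparisons did not use, 32 passed for TIP-1 shRNA minus control when all rows were fitted together (226 passed in all).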

How the results depend on the processing

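The 2-fold requirement, identical rows counted once and both exclusions of genes in runs were chosen after the results were seen. Counts below follow the order TIP-1 shRNA minus control (980 as reported), shRNA 162 (2019), shRNA 159 (537), shRNA 159 minus shRNA 162 (1836) and both hairpins in the same direction (231). With the brighter rows alone the counts were 1992, 3090, 946, 2468 and 477, and with a variance trend 2265, 3482, 1137, 3022 and 533. With all rows they were 226, 691, 111, 593 and 49; the prior degrees of freedom were 2.94 there, 5.31 as reported and 7.04 in the brighter rows. A 2-fold change left 39, 90, 44, 89 and 14. With the 4 shRNA clones as 1 group 71 rows passed and with the hairpin as a random block 27, since the difference between hairpins then adds to the error. Whether the replicate numbers pair the clones stays open. Correlations of deviations between groups were -0.05, 0.26 (control and shRNA 159) and -0.03. A chromosome 19 run was higher in clone 1 than in clone 2 of the control and shRNA 159 groups. On chromosome 1, runs were lower in clone 1 of the control group (LCE5A to LCE1A, median -0.17) and of the shRNA 159 group (FLG to LCE1D, median -0.23). With the replicate numbers as a block the counts were 1011, 2128, 584, 1983 and 250. Quantile normalization, identical rows counted once and leaving out the chromosome 7 run kept the 5 counts within 1.5 times, and so did only the 4 arrays compared for the 3 counts it was run for.

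Leaving out each array in turn gave 187 to 1138, 526 to 2416, 142 to 512, 597 to 1352 and 60 to 228, from fewer arrays; a group left with a lone array is assumed to vary like the others. TAX1BP3 stayed past the threshold under all alternatives run (-1.49 to -1.39 without 1 array, adjusted p up to 0.0227, reached with the hairpin as a random block). The correlation of the hairpins' changes ranged from 0.321 without shRNA 159 clone 1 to 0.506 without control clone 1. For gene lists (8 as reported) the range was 4 without shRNA 159 clone 2 to 8 without shRNA 162 clone 1, the brighter rows gave 6 (0 higher: interferon, extracellular matrix and antigen presentation lost the call, cadherins and adhesion gained it), fry gave 2, and an estimated correlation gave 0. Of 52 results for single genes, 38 never lost the call under the alternatives that gave a value and 0 reversed; 14 lost it, each with the 4 clones as 1 group and with the random block, which were run for the 24 results of TIP-1 shRNA minus control alone. Genes outside the brighter rows had no value there. A pseudocount was not run because the values were already on the log2 scale, and a variance trend was not run for the lists. Causes not named here were not tested. Dim rows lie near background, which limits small changes there; detection calls were not used here.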

Other observations

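The genes below were chosen after their values were seen, and no further test was run on them. Besides the named genes, the rows that passed with the hairpin as a random block included AOX1 (aldehyde oxidase, -1.05 with shRNA 162 and -0.93 with shRNA 159), PSG4 (-1.17 and -0.87), DOK4, a docking protein of receptor kinases (0.82 and 1.09), IGF2BP3, an RNA-binding protein (0.95 and 0.80), and HSPA13 (0.91 and 0.85). None of these 5 passed for the difference between the hairpins (limma adjusted p of 0.434, 0.0902, 0.0744, 0.258 and 0.768). The random block favours rows with a small difference between the hairpins, so this outcome was largely built in.

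Among the 16 rows called in opposite directions, the hypoxia-inducible factor EPAS1 changed by -0.59 with shRNA 162 and 0.93 with shRNA 159, the adhesion protein TENM2 by -0.56 and 1.20, the transcription factor NFIB by -0.53 and 0.75, the matrix protein EFEMP1 by -0.36 and 0.78, and CDK15 by 1.02 and -0.89. Of the 16, 6 lie in runs of neighbouring genes.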
